A study of Sus scrofa with 112 samples.

How the data were processed

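The 112 arrays measured RNA of Semimembranosus muscle, 1 array per animal, in 1 colour (Cy3). Per the file headers, the slides were scanned and read with Agilent Feature Extraction 9.5.3.1, and each scanner file gives the intensity of every spot on a linear scale with background and outlier flags. The authors' deposited value table holds values on a natural log scale. It was tested against the scanner files: each column equals the natural log of the processed signal minus a constant per array, with a largest difference of 7.1e-15. The rule behind the constant is not given in the sources used here. The columns' medians ran from -0.608 to -0.325 on the natural log scale. Values were divided by the natural log of 2 to give log2 units. The scale and direction of the table are thus known, and its exact centring is not.

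The table keeps 6665 of 15198 probes. Every kept probe was well above background on at least 57 arrays and had an SD of at least 0.281 log2, and the rule used to keep them is not given in the sources used here. Of the 746480 values, 5000 (0.67%) are missing. Of the missing values 27.1% are spots with a non-uniform outlier flag in the scanner file, against 0% of the values present. Background brightness had a median between 37 and 52 units per array, and 0 to 19 spots per array were saturated. No column of the table belonged to another series.

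Sex was taken from the labels, and chip from the labels' chip number. The main values were each sample's own column of the value table, because the slide number of the recorded scanner file contradicted the chip label in most samples. As alternatives, the scanner files were taken as recorded, or each was joined to the sample whose column it matched, with log2 of the processed signal minus the array's 75th percentile. Arrays carry a row and a column on the slide in the scanner header, and these were used through the joined files. The p-values rest on separate animals, as the labels number each animal. No litter or family term was fitted, so relatedness among the animals of this F2 cross is not accounted for.

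Comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg). The sex comparison had chip as a fixed block with 13 terms, and differences are samples labelled female minus samples labelled male. The chip test was a moderated F from the sums of squares with and without the chip terms, so that probes with missing values could enter. Variance shares came from the same sums of squares. The spread comparison used the absolute deviation from the median of the sex label after chip was removed. Probes were not averaged by gene. The sex, chip and spread tests were each first tested on simulated data with 200 changed probes and the real residual spread. The residuals of each probe were shuffled separately, so the simulated data lack the correlation between probes. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files.

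The rule for named genes, fixed before the data were examined, took features with a single gene symbol. All probes of the scanner files carry an unknown gene name, and 0 of their 14147 contig accessions matched the gene tables used here. The rule therefore names none, and probes are given by ID. For the same reason, the 21 gene lists, the 2 sex-linked lists among them, the list scores and the chromosome share of calls were not run.

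Probes with 2 levels were sought after the data were seen. For each of the 15198 probes of the joined scanner files, the cut that takes most variance was found. A probe was kept if 2 levels took at least 80% of the variance, each level held at least 8 arrays and the empty interval between them was at least 0.5 log2. In simulated data the rule recovered 100% of probes with a difference of 4 log2 between the levels and 7.46% of those with 2 log2, with 0 false calls. The simulated noise was normal with the same SD for every probe and was not taken from the data. The 0 false calls therefore may not hold for real probes, least of all for those near background.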

Results

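The samples were Semimembranosus muscles, a hind-leg muscle, of 112 pigs of an F2 cross between 2 sire lines. Total RNA of each animal was labelled with Cy3 and hybridised alone to a custom Agilent oligonucleotide array. The labels name 48 samples as female and 64 as male, and the series text calls the males barrows, that is, castrated. The arrays lay on 14 chips of 8, each with samples labelled as both sexes and with 1 to 7 labelled female. They were scanned on 5 days. Each array carried 15198 distinct gene probes, and the deposited value table keeps 6665 of them. Between 9642 and 13205 probes per array were well above background, with a median of 11206.5. The number of arrays limits the precision.

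The value-table columns and the scanner files recorded for the samples did not pair as recorded. Each column equalled the natural log of the scanner's processed signal minus a constant in exactly 1 of the 112 arrays, and no other array came nearer than r = 0.886 over centred values. The matching array was the one recorded for the sample in 4 of 112 samples. The slide number in the scanner header equalled the chip label in 5 samples under the recorded pairing and in 112 under the match by values. The comparisons below used the value-table columns.

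**Figure D1:**
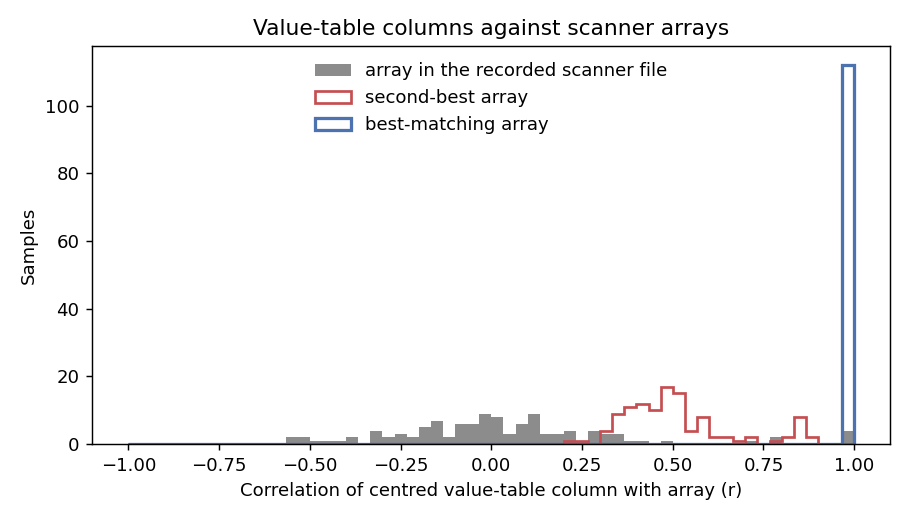
Histogram over the 112 samples of the correlation between each centred value-table column and the array in its recorded scanner file (grey), the second-best array (red outline) and the best-matching array (blue outline). The best-matching arrays lie at r = 1, the second-best reach at most 0.886, and the recorded arrays have a median r of 0.0023.

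The first comparison asked which transcripts differed between samples labelled female and samples labelled male. No probe passed: with chip as a block, limma gave 0 of 6665 probes with an adjusted p under 0.05, and the smallest adjusted p was 0.331. At an unadjusted p under 0.05 there were 337 probes, where 333.25 would be reached by chance, 158 higher and 179 lower in the samples labelled female. For the samples as labelled, the median standard error was 0.0792 log2, and the 95% interval lay between -0.5 and 0.5 log2 for 6409 of the 6665 probes, or 96.2%. In simulated data of the same spread, on 3579 probes, the fit recovered 100% of planted differences of 0.5 log2 and 55.2% of those of 0.25 log2. Each probe was shuffled on its own there, so the correlation between probes was absent and the recovery in the real data may differ. Both the limit from the intervals and the recovery hold only if the labels fit the arrays, and 40 of 112 samples went against a split of the arrays described below.

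The files do not pair the probes with gene names, so no gene is named here, and the probes below, chosen after their values were seen, carry the IDs and 60-base sequences of the array design. The smallest unadjusted p belonged to BX669980.1_324, whose sequence is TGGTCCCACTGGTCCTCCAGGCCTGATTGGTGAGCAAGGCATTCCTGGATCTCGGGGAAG. Its mean was 0.52 ± 0.39 log2 (SD, n = 48) in samples labelled female and 0.81 ± 0.29 log2 (SD, n = 64) in samples labelled male. The blocked difference was -0.30 log2 with a standard error of 0.07 and a limma adjusted p of 0.331, and the mean of the samples labelled female was the lower one on 12 of 14 chips. CB470177.1_1569 had a difference of -0.57 log2 with a standard error of 0.15 and a limma adjusted p of 0.455, lower on 10 of 14 chips. In the other direction, BQ597769.1_2131 had a difference of 0.25 log2 with a standard error of 0.07 and a limma adjusted p of 0.455, higher on 11 of 14 chips. DN109228.1_158 had a difference of 0.30 log2 with a standard error of 0.08 and a limma adjusted p of 0.469, higher on 12 of 14 chips. Fitted within each of the 5 scan days, limma again gave 0 probes with an adjusted p under 0.05, and between 121 and 460 at an unadjusted p under 0.05. Fitted within each of the 12 chips that hold at least 2 samples of each label, limma called 22 probes on chip 68, 4 on chip 69 and 0 on each of the other chips. On both chips with calls the label goes with the column on the slide: on chip 68 all 4 samples labelled female lie on columns 1 and 2 and all 4 labelled male on columns 3 and 4, and on chip 69 both samples labelled female lie on column 3. On each of these chips the calls include the 4 probes with 2 levels described below, both of whose levels occur on every column over the other chips. For the other calls, all on chip 68, label and column cannot be told apart.

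**Figure D2:**
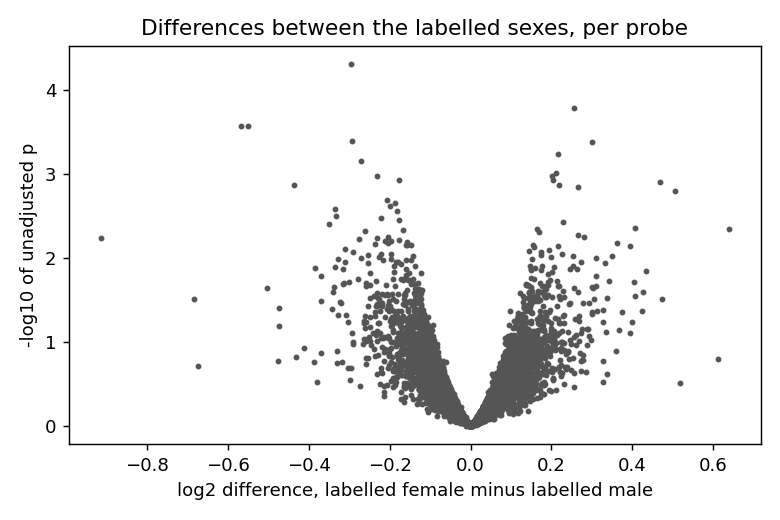
Each point is 1 of 6665 probes, with the log2 difference of samples labelled female (n = 48) minus samples labelled male (n = 64) on the x axis and -log10 of the unadjusted limma p on the y axis. The smallest adjusted p of these probes was 0.331.

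The sex labels went only in part with a split of the arrays in the sizes of the sexes. On 4 probes the arrays fell into 2 levels with an empty interval between them, and all 4 split the arrays in the same way, 48 to 64. On CB286695.1_1794 the lower 48 arrays reached at most -1.79 and the upper 64 began at 0.42 log2 relative to the array's 75th percentile. Of the 48 samples labelled female, 28 were on the side of 48 arrays and 20 on the side of 64. Of the 64 samples labelled male, 20 were on the side of 48 and 44 on the side of 64. The side went with the label in 72 of 112 samples, with a two-sided Fisher's exact p of 0.0066. That test ignores chip, and on each of the 14 chips the number of arrays on the side of 64 equalled the number labelled male. Such equal counts alone raise the agreement, so the p does not show that side and label went together within chips. On chips 68 and 69, and on no other chip, the side went with the label in all 8 samples. The values above are therefore given for the samples as labelled.

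**Figure D3:**
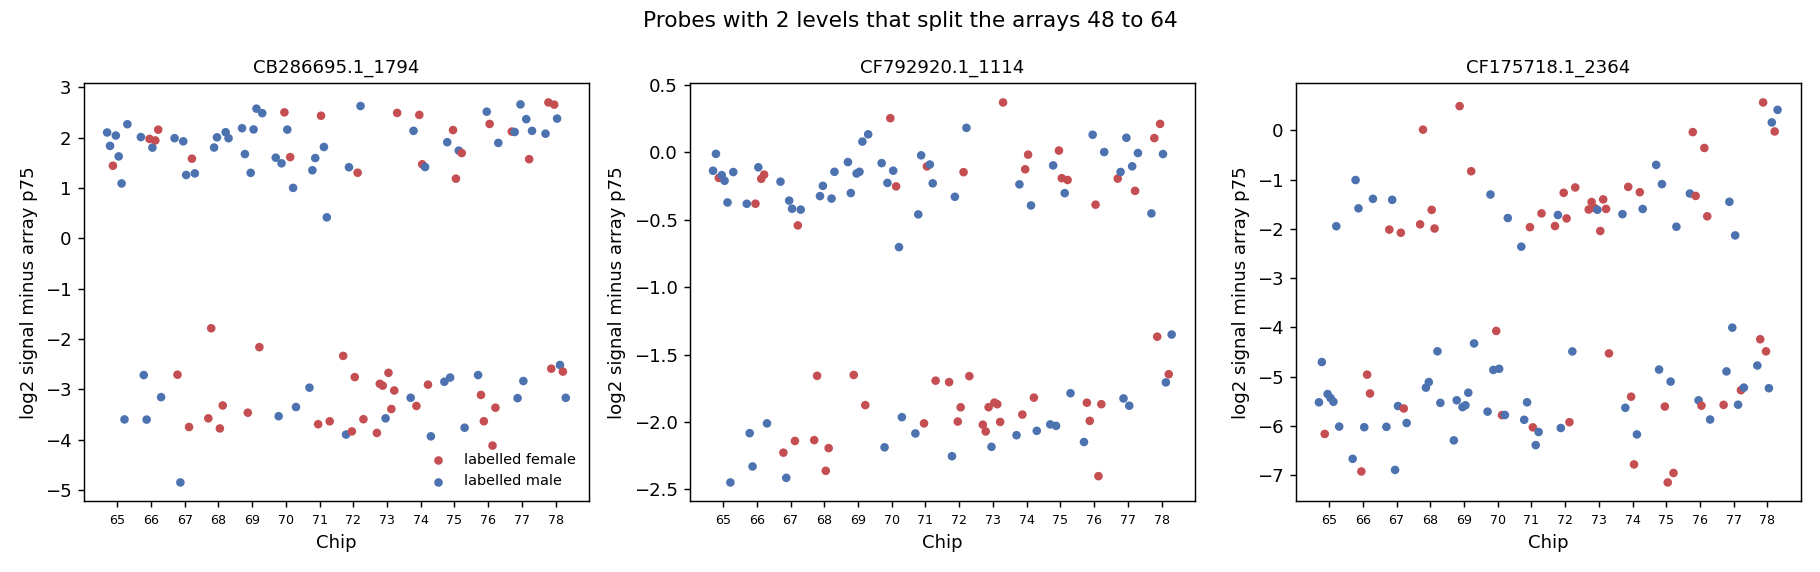
Values of 3 of the 4 probes on each array (log2 signal minus the array's 75th percentile), by chip on the x axis, with samples labelled female in red and labelled male in blue. CB286695.1_1794 and CF792920.1_1114 are higher on 64 arrays and CF175718.1_2364 on the other 48, and both colours occur on both levels.

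The second comparison asked how much of the spread among the 112 animals went with the chip, with the sex label or with neither. Per probe, the median share of the variance was 80.0% for neither, 18.7% for chip and 0.499% for the sex label. The share for the sex label measures sex only if the labels fit the arrays, and 40 of 112 samples went against the split above. A sex difference that the labels miss would count under neither. With 1 array per animal, the share for neither holds differences between animals and error of the array, its position on the slide included. These cannot be told apart here, and the same holds for the residual SD below. Independent normal values with no effect would give medians of 11.3% for chip and 0.415% for the sex label. With 13 chip terms on 112 samples, 2386 of 6665 probes, or 35.8%, had a limma moderated F test of chip with an adjusted p under 0.05. This count fell by over 1.5 times without the 6 arrays of lowest correlation, to 1272 probes. Once chip and sex label were removed, the residual SD had a median of 0.383 log2 and an interquartile range of 0.3146 to 0.4995 log2. The 2 probes with the largest residual SD were BQ598889.1_523 with 3.27 log2 and CB286695.1_1794 with 2.57 log2. The latter is 1 of the 4 probes that split the arrays 48 to 64, so its residual SD holds that split where the labels went against it. The sequence of BQ598889.1_523 is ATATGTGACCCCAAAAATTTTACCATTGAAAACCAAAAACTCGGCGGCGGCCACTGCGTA, its values spanned 7.52 log2, and neither chip nor sex label took more than 1.15% of its variance.

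**Figure D4:**
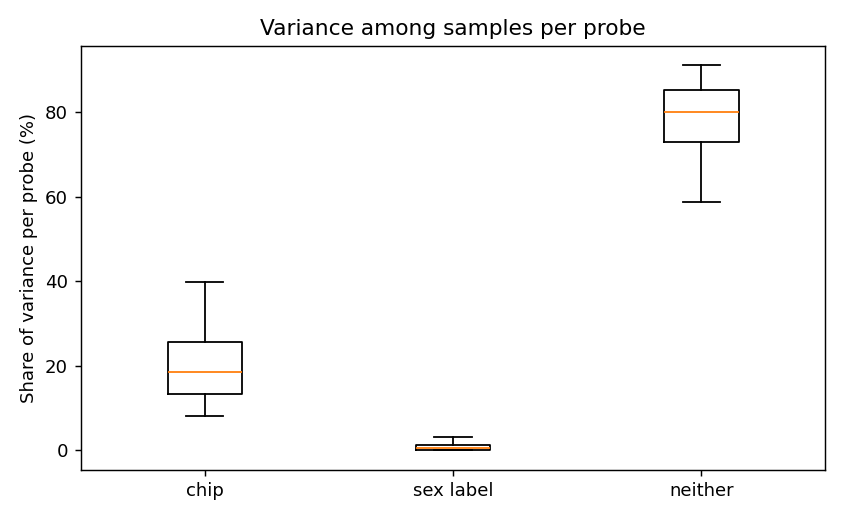
Share of each probe's variance among 112 samples taken by chip, by sex label and by neither, in percent, over 6665 probes. Boxes show the quartiles and the line the median (18.7%, 0.499% and 80.0%), and whiskers run from the 5th to the 95th percentile.

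The largest component of the value table, over the 3579 probes without a missing value, took 31.98% of the variance. Chip accounted for 36.2% of that component, the scan day, which all arrays of a chip share, for 23.2% and the sex label for 1.46%. With no effect, chip would take a median of 11.3%. The second component took 8.13% of the variance. Of it, 46.1% went with the column of the array on its slide and 0.103% with the sex label. For both components the share for the sex label measures sex only if the labels fit the arrays, and 40 of 112 samples went against the split above. Pairs of probes on the same contig gave a measure of precision: over 784 pairs well above background on at least 75% of arrays, the median correlation across the 112 samples was 0.866 and the interquartile range 0.734 to 0.933. The lowest was -0.641, and 8 pairs were under 0. Both probes of a pair lie on the same array, so error shared by an array can raise the correlation too. No pairs of unrelated probes were taken for comparison.

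The third comparison asked whether animals labelled as one sex differed more among themselves than those labelled as the other. Of 6660 probes, limma gave 0 with an adjusted p under 0.05 for the absolute deviation from the median of the sex label, and 256 at an unadjusted p under 0.05. The smallest adjusted p was 0.556, and the median difference in absolute deviation was 0.011 log2. In simulated data on 3579 probes, again without correlation between probes, the test recovered 74% of probes whose SD differed 2-fold and 17% of those with a 1.5-fold SD. As in the first comparison, the result and the recovery hold only if the labels fit the arrays, and 40 samples went against the split above.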

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

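Both results were found only after the values were seen. The value table leaves out 4066 probes that were well above background on all 112 arrays, a signal outside the main measurement. Their median SD was 0.231 log2, against 0.422 log2 for the kept probes. Among the probes left out were also 81 of the 104 probes with 2 separated levels, and the tests that bear on those probes stand under the other observations.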

How the results depend on the processing

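The count of probes between the labelled sexes was 0 under 11 planned settings and 4 chosen after seeing the data (all probes of the array, slide row and column as covariates, the first component as a covariate, and without the 14 arrays described under the other observations). The smallest adjusted p ran from 0.0629, with no chip term, to 1.0, and 215 to 521 of the value table's probes had an unadjusted p under 0.05. The filter on dim probes removed none. The spread comparison between the labelled sexes stayed at 0 under 4 planned settings and 1 chosen later. The chip count of 2386 stayed within 1.5 times with the joined scanner files and with quantile normalization. It was 9 with the scanner files as recorded, whose slides seldom match the chip labels, and 1272 without the 6 arrays of lowest correlation. With 2 settings chosen after seeing the data it was 1512 without the 14 arrays and 5363 over all 15198 probes, where more probes were tested. All 6 arrays of lowest correlation are among the 14, so both falls leave out the same 6 arrays. The cause of the falls was not tested.

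Not run, for want of gene names: the settings for gene lists, sex-linked genes and list scores, the brightest probe per gene, and features with a single symbol. No paired analysis was possible because the replicate numbers only name samples. Signal over background limits 4144 of the probes outside the table, which were well above background on at most 56 arrays.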

Other observations

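All tests in this part were chosen after the results were seen. Random regroupings of the samples decide nothing about a count of 0, which all 100 of 100 splits must reach. The highest other split gave 3 probes for the labelled sexes and 1 for the spread between them. At an unadjusted p under 0.05, 27 of 100 splits, the real one included, gave as many as the 337 probes of the labelled sexes, with a highest other of 1895, so chance was not excluded. For the spread between the labelled sexes 53 of 100 gave as many as 256, with a highest other of 916, and chance was not excluded either. Splits with several times the real count point to a structure of the samples. For chip, 1 of 100 regroupings, the real one, gave 2386 probes and the highest other gave 2. Chance is argued against, as far as 100 regroupings can show.

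The 4 probes that split the arrays 48 to 64 show a pattern against the sex labels in 40 of 112 samples. Levels unrelated to sex are argued against: on 14 of 14 chips the number of arrays on the side of 64 equalled the number labelled male, where permuted labels gave a median of 3 and at most 10 chips (permutation p = 1e-05, the smallest 100000 permutations can give). The pairing of scanner files as recorded is argued against too, with 60 samples going with the label. A candidate explanation is that labels and arrays were exchanged between the 2 rows of each slide: with the rows exchanged, the side went with the label in 112 of 112 samples, and 22 probes other than these 4 passed the threshold, against at most 5 under the 47 other rearrangements of the 2 by 4 slide grid. The exchange leaves the labels of chips 68 and 69 unchanged, the 2 chips where probes were called in the fits within chips. Those calls are no separate evidence: on chip 69 they are only these 4 probes, and for the others on chip 68 label and column cannot be told apart. Samples with rows exchanged are not the samples as labelled, so this stays a hypothesis and no probe is named from it.

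Of 15198 probes, 104 had 2 separated levels. On 50 of them, linked by splits that differ on at most 3 arrays, nearly the same 14 arrays formed the upper level. Of the 50 probes, 44 were well above background on at most 20 arrays and 5 on every array, so the split was not confined to dim probes. The 14 arrays lay on 8 chips, with 6 of the 14 on chip 78, and 0% of 2000 random placements put as many on 1 chip. A chip or scan day as the whole cause is argued against, as all 8 of these chips also held other arrays. A brighter background as the whole cause is argued against by the negative control spots, whose mean was above the median of the other arrays on 5 of the 14 arrays, although the local background itself was above its median there on 9, while the mean of the 2501 probes seldom well above background exceeded the median of the other arrays on all 14. The column on the slide as the whole cause is argued against in the same way as chip, since 3 of the 4 columns held both kinds of array. It stays open as a part of the cause: 0, 4, 4 and 6 of the 14 arrays lay on columns 1 to 4, with a permutation p within chips of 0.0446, not adjusted for the other tests. Whether the sex label goes with them stays open, with 9 labelled female and 5 labelled male (Fisher's exact p = 0.0933). Because the labels went against the split of the 4 probes in 40 of 112 samples, this test cannot decide the question for sex itself. RNA from another tissue could not be tested without gene names.

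The other 50 probes split the arrays in other ways. On 29 of them the upper level held at most 20 arrays, and these 29 were well above background on at most 20 arrays, as were 44 of the 50 above. BQ598889.1_523 held 55 arrays on the lower level and 57 on the upper, with an empty interval of 3.43 log2. BQ597365.1_2337 held 40 and 72, with an empty interval of 3.08 log2. For these 2 probes, a candidate explanation is a sequence difference under the probe that segregates in the cross. It cannot be told apart from a difference in transcript level here, because neither has a second probe on its contig. Only 1 of the 50, BF080032.1_118, has one. That second probe was well above background on all 112 arrays, and the correlation between the pair was -0.013.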
